A study of Mus musculus with 8 samples.

How the data were processed

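RNA-seq gene counts of 8 libraries of CD31-sorted mouse lung endothelial cells were analysed, 4 from wild-type (WT) mice and 4 from mice with an induced endothelial deletion of the complex III subunit QPC (KO), at postnatal day 15. Groups and replicate numbers were taken from the sample labels. Total RNA was extracted with a column kit with DNase treatment, per the labels' protocols, and the library kit is given only as a standard Illumina protocol. Per the submitters' processing notes bcl2fastq, TopHat, HTSeq and edgeR were used with the mouse build mm10, without versions. The annotation release, the strand setting of the counting and the filters are not given in the sources used here, so antisense and overlapping genes cannot be told apart from their partners, and genes with near-identical copies may have lost or shared reads.

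The deposited values are raw read counts per gene, whole numbers with 1 column per library, and the authors' own normalised values and fold changes were not used here. All 8 value columns matched a sample label and 0 columns were left over. The table held 43430 Ensembl gene IDs, of which 42462 had a symbol in the GENCODE annotation of GRCm38, the build called mm10. IDs without a symbol took 0.0792% to 0.101% of each library's counts. Total counts ran from 6407924 to 13981329 per library. No 2 replicates were alike within sampling noise: chi-square per degree of freedom between libraries of a group was 32.4 to 74.6. Reads carry no molecular identifiers, so counting intervals and the floor of 3 counts per library used for genes at 0 cover counting error only.

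Counts were normalised with TMM factors and filtered with filterByExpr (minimum count 10, minimum total 15), which left 12689 genes. KO was compared with WT by the quasi-likelihood F test of edgeR 4.0.16 (robust dispersion and fit, genotype as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05 and no minimum fold. CPM values printed are TMM-normalised, and fold changes are the fitted ones with SE derived from the F statistic. The common biological coefficient of variation was 63.5%. Library totals and shares of counts were compared by exact two-sided permutation tests of the means over all assignments of 4 against 4, whose smallest p is 0.02857, adjusted over 8 measures.

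Before the data were examined 52 gene lists were written (pathways, respiratory complexes, endothelial subtypes and markers of other cells a lung digest could hold). The 50 with 3 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Uqcrq was left out of the complex III list. Members were also counted after adjustment over the list alone. The genes named were fixed by rule at the same time: Uqcrq, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM and all KO libraries on one side of all WT libraries, and up to 4 members with the smallest p from each list described. Unnamed gene models, immunoglobulin and T cell receptor segments and sex-linked genes were left out of the largest changes. Other genes are marked where named.

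The pipeline was tested on simulated counts with the means and library sizes of these samples and 200 changed genes. Their spread was drawn from the dispersions that edgeR fitted to each gene. Of 12025 genes tested, edgeR recovered 0% of those changed 1.5-fold, 19.7% of those changed 2-fold and 40.3% of those changed 4-fold, and 6.82% of its calls were false. DESeq2, on 12689 genes, recovered 53.7% of 4-fold changes with 42.7% false calls, and limma voom, on 12025 genes, 34.3% with 2.78%. As the counts follow edgeR's own dispersions, these shares do not compare the tools on equal terms. Fewer genes were changed in the simulation (200) than were called by edgeR in the data (461). The adjustment is stricter per gene when fewer genes change, so these shares may not carry over to the data.

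Alternatives were other size factors (RLE, upper quartile, totals only), no filter or a stricter one, DESeq2 1.42.0, limma voom with and without sample weights, the replicate number as a block, the level of Y-linked genes as a covariate, removal of mitochondrial and haemoglobin genes, a stricter threshold, a 2-fold minimum and leaving out each library in turn. Added after the data were seen were the alveolar type 2 marker level as a covariate, leaving out both libraries at the ends of the first principal components, thinning to one depth, removal of each library's trend on transcript length and GC content, and edgeR's newer dispersion option (legacy = FALSE). The newer option leaves the input of camera unchanged, so its camera results repeat the main ones. Counts of alternatives given for lists include it all the same. The stricter threshold and the 2-fold minimum were applied only to the counts of changed genes. They are not among the alternatives counted for single genes or lists.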

Results

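RNA was sequenced from lung endothelial cells of C57BL/6 mice at postnatal day 15, after QPC, a subunit of mitochondrial respiratory complex III, had been deleted in the endothelium. QPC was taken here to be the product of Uqcrq. Tamoxifen, the drug that switches on the deletion, was given from postnatal day 0 to day 4, and cells carrying the endothelial surface protein CD31 were sorted from the lungs. Wild-type (WT) and knockout (KO) mice gave 4 libraries each. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. Each group held libraries with Y-linked transcripts and libraries nearly without them, and so came from more than 1 animal. Total counts per library ran from 6407924 in WT replicate 3 to 13981329 in KO replicate 4, and the other 3 WT libraries held 11607842 to 11951816.

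The comparison of KO with WT asks which transcripts of lung endothelial cells differ after loss of this complex III subunit. Uqcrq itself (ENSMUSG00000044894), which lies on the minus strand of chromosome 11 from 53427922 to 53430831 in GRCm38 (mm10), was measured first. Its transcript Uqcrq-201 has 2 exons, and the sources used here do not state which part of the gene is deleted, so gene-level counts can hold reads from outside that part. Normalised Uqcrq expression was 26.3, 24.5, 26.8 and 31.5 CPM (normalised read counts per library size) in WT replicates 1 to 4 and 1.59, 15.6, 9.57 and 14.0 CPM in KO replicates 1 to 4. The means were 27.3 ± 3.01 CPM in WT and 10.2 ± 6.26 CPM in KO (SD, n = 4 each), so that KO held 37.3% of the WT level and all 4 KO libraries lay below all 4 WT libraries. An exact two-sided permutation test of the mean CPM gave p = 0.02857, the smallest that 4 against 4 can give. In the transcriptome-wide test the log2 fold change of -1.42 (SE 0.53) did not pass the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.179). For this gene alone, which was named in advance, the edgeR p before adjustment over all genes was 0.0165.

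In the KO cells, 9 of 28 genes of amino acid synthesis and targets of the stress response factor ATF4 were called higher and 0 lower, among them Mthfd2, a mitochondrial folate enzyme, at 73.9 ± 32.5 CPM against 4.70 ± 0.672 CPM in WT (SD, n = 4 each). Of 80 cytosolic ribosomal protein genes 61 were called higher, as were 12 of 20 cytosolic tRNA synthetase genes, with 0 lower in either list. Of 12 markers of general capillary endothelium 6 were called lower, as were 3 of 12 Notch pathway genes. All 5 lists passed camera, a gene set test, and with an estimated correlation the tRNA synthetases had an adjusted p of 0.0391, which passed in 9 of 23 alternatives, and each of the other 4 lists 0.121. In all, 461 of 12689 genes tested changed, 285 higher and 176 lower in KO (edgeR with Benjamini-Hochberg adjustment at 0.05). The median change among them was 1.86-fold in either direction, and 190 changed 2-fold or more, 114 of them higher. All 4 KO libraries lay on one side of all 4 WT libraries for 449 of the 461 genes. Over all genes tested 1474 were separated in this way, 11.6% against 2.86% by chance. The count was 270 (173 higher, 97 lower) without KO replicate 3, and lower genes numbered 105 without KO replicate 2 and 111 without WT replicate 2. With each library's trend on transcript length and GC content removed, a setting chosen after the data were seen, 285 genes changed, 129 higher and 156 lower.

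**Figure D1:**
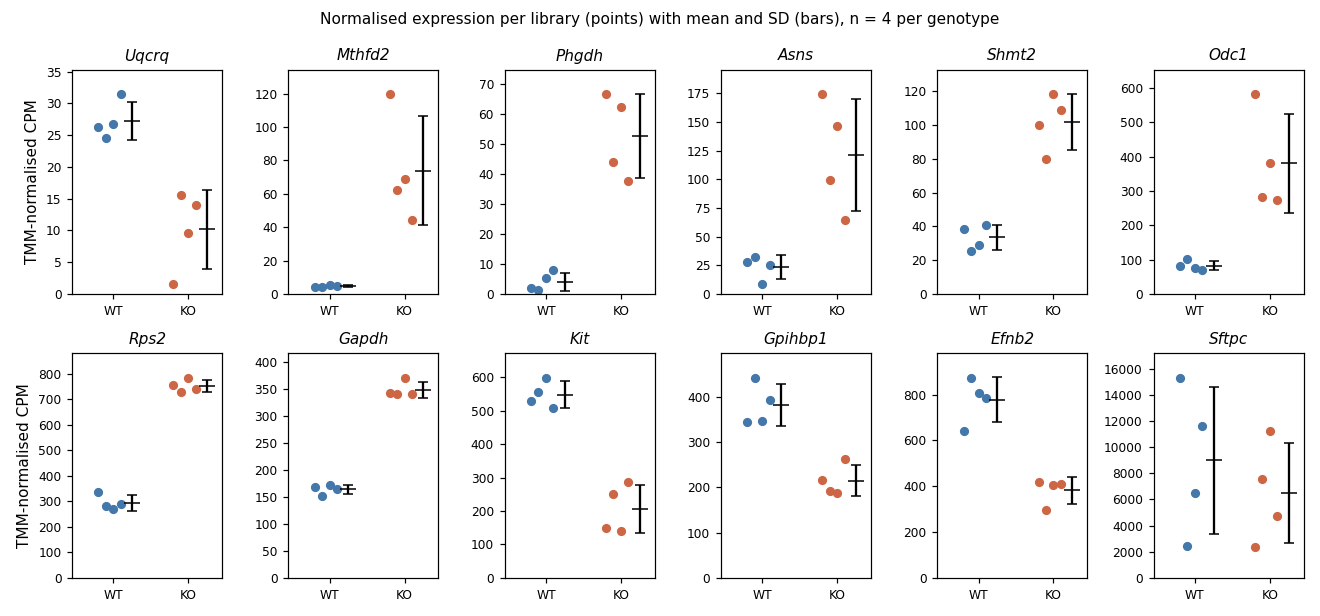
TMM-normalised expression in CPM (linear axes from 0) of 12 genes in each of the 4 WT (blue) and 4 KO (orange) libraries, with the mean and SD as bars. Uqcrq, Kit, Gpihbp1 and Efnb2 lay lower in every KO library than in every WT library, and Mthfd2, Phgdh, Asns, Shmt2, Odc1, Rps2 and Gapdh lay higher, whereas the 2 groups overlapped for Sftpc, a marker of alveolar type 2 cells.

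ATF4 is the transcription factor of the integrated stress response. The list of its targets and amino acid synthesis genes had 9 of 28 members higher and 0 lower (10 when adjusted over the list alone), with a median log2 fold change of 1.22. Phgdh, the first enzyme of serine synthesis, rose from 4.07 ± 3.09 to 52.7 ± 14.0 CPM (log2 fold change 3.70, SE 0.51, edgeR adjusted p = 0.000873). Mthfd2 rose by 3.98 (SE 0.35, edgeR adjusted p = 3.16e-05) and Shmt2, the mitochondrial serine hydroxymethyltransferase, by 1.60 (SE 0.23, edgeR adjusted p = 0.000906) on the log2 scale. Eif4ebp1, which encodes a repressor of cap-dependent translation, rose by 1.90 (SE 0.29, edgeR adjusted p = 0.00141) on the log2 scale. The other members called higher were Aldh18a1, Asns, Chac1, Gdf15 and Pycr1, of which Aldh18a1 and Pycr1 were picked out after their values were seen. Pycr1, an enzyme of proline synthesis, had 0 counts in every WT library and 5.98 ± 2.39 CPM in KO, at least 19.8-fold higher than a floor of 3 counts per library. The list passed as higher (camera adjusted p = 5.33e-14, but adjusted p = 0.121 with an estimated correlation). Of 17 amino acid transporter genes 1 rose, the same number as when adjusted over the list alone. It was Slc7a1, a cationic amino acid transporter (log2 fold change 1.27, SE 0.28, edgeR adjusted p = 0.0166). Slc7a5, a leucine transporter, had 108 ± 36.5 CPM in KO and 7.25 ± 8.38 CPM in WT and did not pass (edgeR adjusted p = 0.132). It passed without WT replicate 2 (edgeR adjusted p = 0.0123), by DESeq2 (0.0307), by limma voom (0.0321) and with edgeR's newer dispersion option (1.52e-05), and reached 0.289 without KO replicate 3. The transporter list passed camera at adjusted p = 0.0436 (adjusted p = 0.23 with an estimated correlation). Its adjusted p was 0.0541 without KO replicate 1 and 0.0715 without KO replicate 4, and Slc7a1 had 0.0621 without KO replicate 3 and 0.0613 without WT replicate 1. Over all alternatives the list ranged from 0.00825 to 0.23 and Slc7a1 from 0.00056 to 0.0702.

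Cytosolic tRNA synthetases, which charge tRNAs with amino acids, had 12 of 20 members higher (15 when adjusted over the list alone) and a median log2 fold change of 0.96. Vars rose from 61.6 ± 11.5 to 153 ± 15.2 CPM (log2 fold change 1.31, SE 0.18, edgeR adjusted p = 0.000873). Sars rose from 105 ± 29.5 to 241 ± 33.4 CPM, Gars from 136 ± 33.0 to 285 ± 47.9 CPM and Eprs from 83.2 ± 16.3 to 172 ± 24.0 CPM. This was the 1 list of 50 tested that passed both with the preset correlation (camera adjusted p = 1.51e-16) and with an estimated one (adjusted p = 0.0391 with an estimated correlation). The latter call ended without any 1 library but WT replicate 3 (adjusted p from 0.0547 without KO replicate 2 to 0.142 without WT replicate 4). It also ended by limma voom without (0.0644) or with (0.0989) sample weights, with WT replicate 3 and KO replicate 1 both left out (0.139), with the replicate block (0.32), with the Y-linked (0.102) or alveolar type 2 (0.0631) level as a covariate and with the length and GC trend removed (0.124), in a range from 0.00921. Cytosolic ribosomal protein genes had a median log2 fold change of 0.65, and 77 of 80 were higher when adjusted over the list alone (camera adjusted p = 6.48e-59, adjusted p = 0.121 with an estimated correlation). Rps2 rose from 294 ± 30.0 to 753 ± 24.0 CPM, Rpl12 from 237 ± 51.1 to 526 ± 19.8 CPM and Rps3 from 538 ± 72.2 to 1014 ± 42.6 CPM. Together these genes took 2.61 ± 0.295% of counts in WT and 4.06 ± 0.101% in KO (SD, n = 4 each, exact permutation p = 0.02857, adjusted p = 0.114 over 8 library measures). Ribosomal protein genes share reads with processed pseudogenes, so the value of any single one is uncertain. After removal of the length and GC trend 20 of the 61 called members were still called, with the list's median at 0.43.

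Among genes of nucleotide synthesis 6 of 27 rose and 0 fell (12 higher and 1 lower when adjusted over the list alone). Their median log2 fold change was 0.80 (camera adjusted p = 4.9e-08, adjusted p = 0.155 with an estimated correlation). Cad, which starts pyrimidine synthesis, rose from 43.3 ± 5.59 to 99.9 ± 21.3 CPM, and Impdh2, an enzyme of guanine nucleotide synthesis, from 46.5 ± 4.98 to 97.3 ± 15.2 CPM. Got1, the cytosolic aspartate aminotransferase, rose from 5.16 ± 2.69 to 29.7 ± 13.7 CPM. Glycolysis genes had 5 of 21 members higher and 0 lower (11 higher when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 7.29e-08, adjusted p = 0.122 with an estimated correlation, and 0.0253 when the alveolar type 2 level was a covariate too). Gapdh rose from 165 ± 8.25 to 350 ± 15.0 CPM, Pgk1 from 45.5 ± 6.13 to 116 ± 17.3 CPM and Pkm from 369 ± 59.9 to 672 ± 37.1 CPM. Gpi1 rose from 234 ± 51.5 to 392 ± 28.0 CPM, a call lost when WT replicate 3 and KO replicate 1 were both left out (edgeR adjusted p = 0.0517, in a range from 0.000514), and the fifth was Eno1, named after its value was seen. Gapdh has many processed pseudogenes and is uncertain for that reason.

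Among genes of the mitochondrial unfolded protein response, chaperones and proteases made when mitochondrial proteins misfold, 1 of 15 rose (2 when adjusted over the list alone). It was Hspa9, the mitochondrial Hsp70, from 109 ± 14.2 to 256 ± 5.05 CPM (log2 fold change 1.23, SE 0.15, edgeR adjusted p = 0.000228). Hspd1, the partner chaperonin, had 77.1 ± 19.6 CPM in WT and 123 ± 21.1 CPM in KO and did not pass (edgeR adjusted p = 0.0962, in a range from 0.0482 with the newer dispersion option to 0.34). The list's median was 0.48 (camera adjusted p = 0.000334, adjusted p = 0.121 with an estimated correlation). Of the 9 other complex III subunit genes 0 passed singly, also when adjusted over the list alone, by edgeR with Benjamini-Hochberg adjustment. Their median log2 fold change was 0.38, with Uqcrh at 107 ± 5.30 CPM in KO and 77.4 ± 8.85 CPM in WT. The list passed camera as higher (adjusted p = 0.0277, adjusted p = 0.321 with an estimated correlation). That call ended without WT replicate 2 (adjusted p = 0.0764), WT replicate 3 (0.0504), KO replicate 2 (0.0553) or KO replicate 4 (0.0558), and with the length and GC trend removed (0.523, the highest of a range that started at 0.0116). Of 13 protein genes of the mitochondrial genome 3 rose (4 when adjusted over the list alone): mt-Co1 by 0.60, mt-Nd1 by 0.53 and mt-Nd2 by 0.48 on the log2 scale. The list passed as higher (camera adjusted p = 0.00825, adjusted p = 0.46 with an estimated correlation). This call ended without KO replicate 2 (adjusted p = 0.0553) and with the length and GC trend removed (0.678, in a range from 0.000553 to 0.678). Leaving out 1 library ended the 3 single calls too, with edgeR adjusted p of up to 0.0707 for mt-Co1, 0.0946 for mt-Nd1 and 0.102 for mt-Nd2, each without WT replicate 3. The calls also ended without WT replicate 2 or KO replicate 2, those of mt-Nd1 and mt-Nd2 without WT replicate 4 or KO replicate 1, and that of mt-Nd2 without KO replicate 3. Removal of the length and GC trend ended all 3, with log2 fold changes of 0.45 for mt-Co1 (edgeR adjusted p = 0.188), 0.27 for mt-Nd1 (0.566) and 0.24 for mt-Nd2 (0.622). Lists of complex I (camera adjusted p = 0.00604), complex IV (0.0266), complex V (0.000343), mitochondrial ribosomal proteins (0.00479) and the TCA cycle (0.00901) also passed as higher, but had adjusted p of 0.455, 0.455, 0.455, 0.355 and 0.32 with an estimated correlation. By edgeR 1 gene was called in complex I, Ndufa11, 1 in the TCA cycle, the citrate synthase gene Cs, and 0 in the other 3. The call of Ndufa11 ended without any 1 library but WT replicate 2 (edgeR adjusted p up to 0.139 without KO replicate 4) and that of Cs without any but WT replicate 1 (up to 0.0977 without WT replicate 4). Both ended with the length and GC trend removed too (0.265 and 0.166, in ranges from 0.00352 and 0.00452). When adjusted over the list alone 3 rose in complex IV and 4 in complex V, with the other numbers as before. The complex IV list had a median of 0.36 but a mean of -0.06. Without WT replicate 2 complex I (0.0616), complex IV (0.139) and the mitochondrial ribosomal proteins (0.0603) did not pass, nor did complex IV without WT replicate 3 (0.0531) or KO replicate 4 (0.0665), nor the TCA cycle without WT replicate 4 (0.0528). Removal of the length and GC trend ended the calls of complex I (0.474), complex IV (0.595), complex V (0.0556) and the TCA cycle (0.124). Complex II (camera adjusted p = 0.452) and complex III assembly (0.606) did not pass.

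Cell cycle genes lay higher as lists by camera with the preset correlation, with few single calls. Neither list passed by fry (adjusted p = 0.0823 for mitosis and G2/M, 0.0812 for DNA replication and S phase). Of 40 genes of mitosis and G2/M 2 rose (15 when adjusted over the list alone), with a median log2 fold change of 0.85 (camera adjusted p = 6.36e-10, adjusted p = 0.339 with an estimated correlation). They were Plk1, a mitotic kinase, from 13.6 ± 4.34 to 39.9 ± 13.5 CPM, and Ckap2l, a spindle protein gene, from 15.0 ± 6.53 to 41.9 ± 15.1 CPM. Of 44 genes of DNA replication and S phase 2 rose, the same number as when adjusted over the list alone, with a median of 0.75 (camera adjusted p = 1.41e-07, adjusted p = 0.351 with an estimated correlation). They were Mcm6, part of the replicative helicase, from 68.6 ± 14.0 to 150 ± 34.7 CPM, and Uhrf1, which maintains DNA methylation at replication, from 24.9 ± 6.37 to 63.6 ± 33.2 CPM. The edgeR call of Plk1 was lost without WT replicate 1 or 3 or KO replicate 2 or 4 (adjusted p up to 0.108, without KO replicate 2). That of Ckap2l was lost without any library but WT replicate 2, and that of Uhrf1 without any but KO replicates 1 and 3 (adjusted p up to 0.172 and 0.186, both without KO replicate 4). Mcm6 held in all 24 alternatives.

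General capillary markers, those of the lung capillary cells that maintain the vessel bed, had 6 of 12 members lower and 0 higher (6 lower and 1 higher when adjusted over the list alone). Their median log2 fold change was -0.75 (camera adjusted p = 1.67e-09, adjusted p = 0.121 with an estimated correlation, and 0.0253 when the alveolar type 2 level was a covariate too). Kit, a receptor tyrosine kinase, fell from 548 ± 39.7 to 206 ± 73.0 CPM (log2 fold change -1.41, SE 0.21, edgeR adjusted p = 0.00141). Cadm1, a cell adhesion protein gene, fell from 192 ± 29.1 to 67.3 ± 24.1 CPM, and Hmcn1 from 449 ± 94.8 to 223 ± 39.4 CPM. Gpihbp1, which carries lipoprotein lipase to the capillary lumen, fell from 382 ± 46.2 to 215 ± 34.0 CPM. Ptprb and Glp1r also fell, and the member higher over the list alone was Cd93, at 4179 ± 1288 CPM in KO and 2943 ± 277 CPM in WT (these 3 were named after their values were seen). Mast cell and basophil markers passed as lower too, on 3 tested of 10 listed (median -0.87, camera adjusted p = 0.0175, adjusted p = 0.23 with an estimated correlation). With no low-count filter that list had a median of -0.04 and an adjusted p of 0.341, in a range from 0.00242. Of the 3 genes 1 fell (2 when adjusted over the list alone): Gata2, a transcription factor gene that endothelial cells also express, from 375 ± 94.9 to 203 ± 50.2 CPM. Its edgeR adjusted p was 0.0158, and 0.0614 without WT replicate 2, 0.0565 without KO replicate 2, 0.053 without KO replicate 3 and 0.0611 with the length and GC trend removed (from 0.000329). Kit is known in mast cells as well. Markers of aerocytes, the gas-exchange capillary cells, did not pass as a list (camera adjusted p = 0.513), except without KO replicate 3 (0.0412, in a range up to 0.912). Of its 12 members 1 fell (3 lower and 1 higher when adjusted over the list alone). It was Ednrb, the endothelin B receptor gene, from 506 ± 10.9 to 306 ± 73.4 CPM. Its edgeR adjusted p was 0.0173 (0.0545 without WT replicate 4, the highest of a range that started at 0.000652). Notch pathway genes had 3 of 12 lower and 0 higher (4 lower when adjusted over the list alone). Their median was -0.43 (camera adjusted p = 6.17e-05, adjusted p = 0.121 with an estimated correlation). Efnb2, an arterial ephrin gene, fell from 778 ± 97.5 to 383 ± 59.0 CPM, and Hey1, a Notch-induced repressor gene, from 231 ± 57.1 to 111 ± 5.92 CPM. Dll4, a Notch ligand gene, fell from 379 ± 63.4 to 219 ± 30.6 CPM.

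Of 26 pan-endothelial genes 5 fell and 1 rose (6 lower and 1 higher when adjusted over the list alone). Calcrl, the receptor gene for adrenomedullin, fell from 3587 ± 282 to 1862 ± 246 CPM, and Tmem100 from 1584 ± 86.5 to 902 ± 205 CPM. Tek, the angiopoietin receptor gene, fell from 941 ± 134 to 583 ± 64.2 CPM. Erg fell from 314 ± 46.1 to 197 ± 32.1 CPM, a call lost without WT replicate 1 or 2 or KO replicate 2 or 3 (edgeR adjusted p up to 0.0872 without KO replicate 2, in a range from 0.00112). The list's median was -0.04, and it passed as lower (camera adjusted p = 0.00825, adjusted p = 0.455 with an estimated correlation). Without KO replicate 2 its adjusted p was 0.0613 and its median 0.0047 (range of adjusted p over all alternatives from 4.83e-05 to 0.455). These genes took 2.82 ± 0.106% of counts in WT and 2.35 ± 0.230% in KO (SD, n = 4 each, exact permutation p = 0.02857, adjusted p = 0.114). Of 11 venous markers 2 fell, as they did when adjusted over the list alone: Slc6a2, the noradrenaline transporter gene, from 419 ± 49.1 to 180 ± 50.0 CPM, and Amigo2 from 123 ± 24.9 to 64.9 ± 5.25 CPM. The edgeR adjusted p of Amigo2 was 0.0103, and 0.0513 without KO replicate 3, in a range from 0.000129 to 0.0547. The venous list passed as lower (camera adjusted p = 0.00901, adjusted p = 0.256 with an estimated correlation). Of 14 arterial markers 2 fell (4 when adjusted over the list alone), Efnb2 and Hey1, which the Notch list also holds. The arterial list had a median of -0.11 and passed as lower (camera adjusted p = 0.00825, adjusted p = 0.455 with an estimated correlation). Its call ended without KO replicate 2 (adjusted p = 0.143, in a range from 0.000168 to 0.455).

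**Figure D2:**
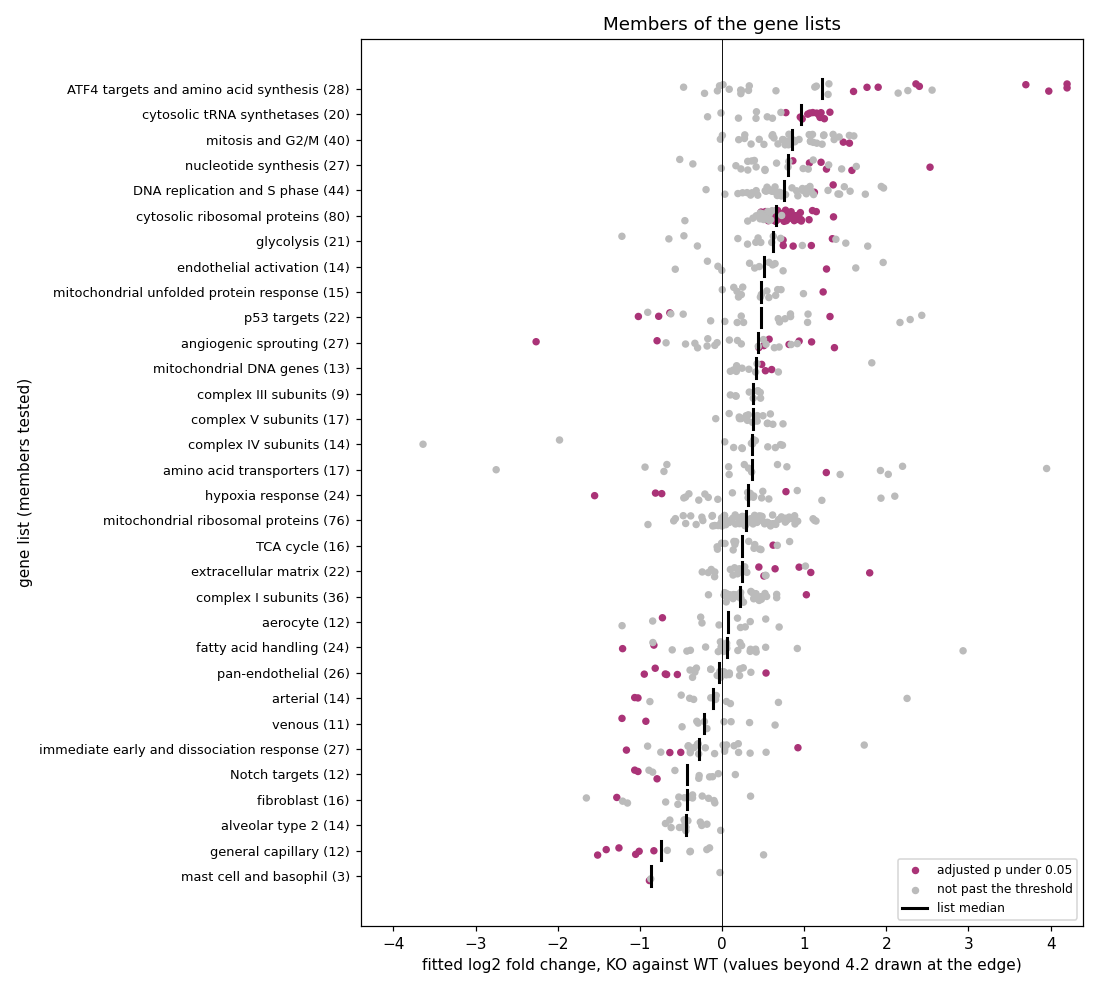
Fitted log2 fold change, KO against WT, of every tested member (points) of 32 of the 50 gene lists tested, those described here by their members, with purple points for members past an edgeR adjusted p of 0.05 and a black bar at each list's median. The ATF4 and tRNA synthetase lists sit highest, with medians of 1.22 and 0.96, and the mast cell and basophil list (3 genes) and the general capillary list lowest, with medians of -0.87 and -0.75. Vertical scatter within a list has no meaning, and Gdf15 and Pycr1 are drawn at the right edge.

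Extracellular matrix genes had 6 of 22 members higher and 0 lower (9 higher when adjusted over the list alone), with a median log2 fold change of 0.25 (camera adjusted p = 6.17e-05, adjusted p = 0.308 with an estimated correlation). Hspg2 (perlecan) rose from 591 ± 73.2 to 1250 ± 112 CPM, Col18a1 from 115 ± 26.4 to 401 ± 166 CPM and Lamc1 from 622 ± 49.3 to 974 ± 114 CPM. Col4a1 rose from 5421 ± 292 to 7719 ± 1246 CPM, a call lost without any 1 of WT replicates 1 to 4 or KO replicate 3 (edgeR adjusted p up to 0.107 without KO replicate 3) and with the length and GC trend removed (0.0891, in a range from 0.00189 to 0.11). Among angiogenic sprouting genes 7 of 27 rose and 2 fell (11 higher and 2 lower when adjusted over the list alone), with a median of 0.44. Plaur, the urokinase receptor gene, rose from 65.7 ± 6.60 to 140 ± 21.3 CPM and Mcam from 923 ± 114 to 1625 ± 321 CPM. The call of Mcam ended with the length and GC trend removed (log2 fold change 0.67, edgeR adjusted p = 0.107, in a range from 1.48e-05). Cxcr4, the receptor gene for Cxcl12, fell from 127 ± 81.8 to 26.5 ± 6.06 CPM, and Dll4 fell too. That list passed as higher (camera adjusted p = 0.0396, adjusted p = 0.46 with an estimated correlation). Its call ended without WT replicate 1 (adjusted p = 0.153), WT replicate 4 (0.0948), KO replicate 1 (0.161) or KO replicate 3 (0.0577), in a range from 0.00966 to 0.46 over all alternatives. It ended as well with RLE size factors (0.0547), library totals (0.0512), the replicate block (0.0659), the alveolar type 2 level as a covariate (0.0858), WT replicate 3 and KO replicate 1 both left out (0.135) and the length and GC trend removed (0.115). With the estimated correlation and fry (0.0823) it was lost in 12 of 26 alternatives. Of 14 endothelial activation genes 1 rose (2 when adjusted over the list alone), the adhesion molecule gene Icam1, from 145 ± 22.5 to 351 ± 126 CPM. The list passed as higher (camera adjusted p = 0.0429, adjusted p = 0.329 with an estimated correlation). Without any 1 library but KO replicate 2 or 4 it did not pass (adjusted p up to 0.134 without KO replicate 1, in a range from 0.0138), and it passed in 11 of 26 alternatives.

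Hypoxia response genes did not move one way as a list (camera adjusted p = 0.987). Of 24 members 1 rose and 3 fell (3 higher and 3 lower when adjusted over the list alone). Hilpda, a lipid droplet protein gene, fell from 137 ± 18.7 to 46.8 ± 7.56 CPM, and Epas1, a hypoxia-inducible factor gene, from 4325 ± 1103 to 2467 ± 388 CPM. With the replicate block the call of Epas1 ended (log2 fold change -0.79, edgeR adjusted p = 0.0545, in a range from 5.64e-05). Bnip3l, a mitophagy receptor gene, fell from 216 ± 27.9 to 130 ± 8.68 CPM. Hif1a rose from 106 ± 14.1 to 181 ± 54.1 CPM. Its edgeR adjusted p was 0.0407, and from 0.0595 to 0.114 without any 1 of WT replicates 1 to 4 and KO replicates 1 and 3 (range over all alternatives 0.00754 to 0.187). That of Bnip3l was 0.00977, and 0.0513 without KO replicate 3, the highest of a range from 2.54e-05. The p53 target list did not pass either (camera adjusted p = 0.13, and 0.0399 without KO replicate 4, in a range up to 0.46), with Phlda3 higher and Plk2, Sesn1 and Btg2 lower among 22 members (7 higher and 4 lower when adjusted over the list alone). Phlda3, an Akt inhibitor gene, rose from 85.2 ± 24.2 to 212 ± 59.5 CPM and Plk2 fell from 799 ± 80.4 to 468 ± 97.4 CPM. The call of Sesn1 was lost without any library but WT replicate 3 or KO replicate 1, and that of Btg2 without any but KO replicate 4 (edgeR adjusted p up to 0.126 without KO replicate 3 and 0.157 without KO replicate 2). Of 24 genes of fatty acid handling 2 fell, as when adjusted over the list alone: Cd36, a fatty acid transporter gene, from 2510 ± 219 to 1085 ± 280 CPM, and Gpihbp1 (camera adjusted p = 0.851 for the list).

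Of the 27 immediate early and dissociation response genes, which sorting can induce, 1 rose and 3 fell, as when adjusted over the list alone. Egr1 fell from 617 ± 134 to 276 ± 42.3 CPM and Hsp90aa1 rose from 123 ± 10.9 to 233 ± 26.8 CPM. Jun and Btg2 were called lower too, though the call of Jun was lost without any library but KO replicate 3 and that of Btg2 without any but KO replicate 4 (edgeR adjusted p up to 0.137 and 0.157, both without KO replicate 2). The list passed as lower (camera adjusted p = 0.038, adjusted p = 0.632 with an estimated correlation). The list's call ended without WT replicate 1 (adjusted p = 0.126), WT replicate 2 (0.206), KO replicate 1 (0.0854) or KO replicate 2 (0.162), in a range from 0.00195 to 0.632. Alveolar type 2 marker RNA was present in every library, at 0.384% to 2.41% of counts. It averaged 1.43 ± 0.872% in WT and 0.999 ± 0.578% in KO (SD, n = 4 each, exact permutation p = 0.429). Of its 14 genes 0 passed by edgeR with Benjamini-Hochberg adjustment, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.113). It passed as lower without WT replicate 2 (0.00022) or KO replicate 3 (0.00153), by limma voom (0.0362) and with the length and GC trend removed (0.0433), in a range up to 0.9. Of 16 fibroblast markers 1 fell, as when adjusted over the list alone: Mfap4, a matrix protein gene, from 142 ± 15.4 to 58.2 ± 7.85 CPM (camera adjusted p = 0.0013, adjusted p = 0.23 with an estimated correlation). Macrophage and monocyte (camera adjusted p = 0.858), pericyte and smooth muscle (0.414), lymphatic endothelial (0.533), alveolar type 1 (0.963), airway epithelial (0.598), B cell (0.924), platelet (0.409), erythroid (0.464) and mesothelial (0.535) markers did not pass as lists, and mast cell and basophil markers passed as lower (0.0175). Lymphatic markers passed as lower without KO replicate 1 (0.00332), with WT replicate 3 and KO replicate 1 both left out (0.00426) and by limma voom with sample weights (0.0491). Pericyte and smooth muscle markers passed as lower without WT replicate 2 (0.0139). Platelet markers passed as higher without KO replicate 1 (0.043) and with WT replicate 3 and KO replicate 1 both left out (0.0472). In all 27 of the 50 lists tested passed camera with the preset correlation, 19 higher and 8 lower in KO, and 1 of them passed with an estimated correlation.

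**Figure D3:**
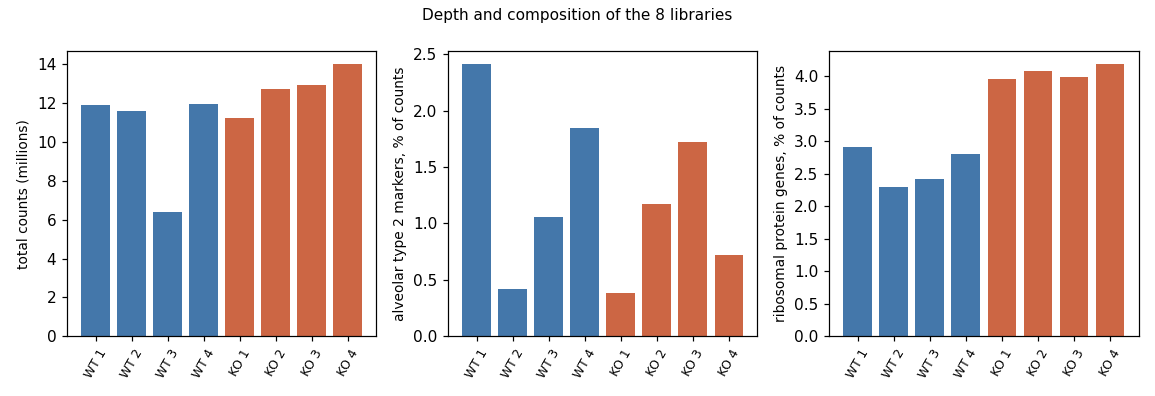
Total counts, and the percent of counts on alveolar type 2 markers and on cytosolic ribosomal protein genes, as bars from 0 for each WT (blue) and KO (orange) library. WT replicate 3 was the shallowest at 6407924 counts, the alveolar type 2 share spread from 0.384% to 2.41% across both groups, and the ribosomal protein share was 2.30% to 2.91% in WT and 3.97% to 4.18% in KO.

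The 12 largest rises with all KO libraries above all WT libraries included, besides Mthfd2, Phgdh, Got1, Asns (log2 fold change 2.36) and Chac1 (2.40), the stress cytokine gene Gdf15. It had 0 counts in 3 WT libraries, 24 in WT replicate 4 and 206 to 1444 in the KO libraries. The polyamine enzymes Odc1 and Srm rose by 2.21 and 3.24 on the log2 scale. Timp3, a metalloproteinase inhibitor gene, rose from 277 ± 22.1 to 1322 ± 543 CPM (log2 fold change 2.25, SE 0.24, edgeR adjusted p = 0.00038). The matrix protein gene Vwa1 rose by 3.41, the secreted glutathione peroxidase gene Gpx3 by 2.52 and Tmem255a by 2.85. Among the 12 largest falls were Slc16a9, a carnitine and creatine carrier gene, from 124 ± 24.8 to 27.6 ± 7.28 CPM (log2 fold change -2.16, SE 0.24, edgeR adjusted p = 0.000207), Cxcr4 (-2.26) and Scube1 (-1.69). The others were the zinc finger genes Zfp641 (-2.67) and Zfp157 (-2.01), the interferon-inducible Ifi208 (-2.35) and Iigp1 (-1.82), the noncoding AU020206 (-2.42), Fmo5 (-1.94), Lrrn3 (-1.93), the circadian factor gene Dbp (-1.71) and Fam13c (-1.68). Interferon response genes did not pass as a list (camera adjusted p = 0.851), with 1 of 26 members called higher and 1 lower. Zfp641, Zfp157, Ifi208 and Iigp1 belong to families of similar genes that can share reads and are uncertain. The calls of 10 of these 24 genes held in all 24 alternatives: Mthfd2, Phgdh, Vwa1, Gpx3, Asns, Timp3, Odc1, Ifi208, Slc16a9 and Scube1.

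Leaving out 1 library ended 13 of the other calls by edgeR. Without KO replicate 3 the adjusted p was 0.113 for Gdf15 (range over all alternatives 0.00559 to 0.261) and 0.0753 for Got1 (0.000312 to 0.136), and without KO replicate 1 it was 0.119 for Chac1 (0.000597 to 0.136). Without WT replicate 1 it was 0.0801 for Srm (from 2.15e-05) and 0.0675 for Fam13c (from 0.000602). Without WT replicate 2 it was 0.0666 for Zfp641 (3.4e-05 to 0.128), 0.12 for Zfp157 (from 0.000523), 0.0902 for Iigp1 (from 0.000491) and 0.0811 for Lrrn3 (from 0.000686). Without WT replicate 4 it was 0.108 for Tmem255a (2.01e-05 to 0.122), 0.081 for AU020206 (from 0.000312), 0.14 for Dbp (from 0.00119) and 0.223 for Fmo5 (from 0.00158). Other single libraries ended the call too for 11 of the 13. These were WT replicates 1 to 3 and KO replicates 1 and 2 for Gdf15, WT replicates 1 and 2 and KO replicates 2 and 3 for Chac1 and WT replicates 2 and 4 and KO replicates 2 to 4 for Srm. They were WT replicate 3 and KO replicates 2 to 4 for Fam13c and WT replicates 1 and 3 and KO replicates 2 and 3 for Zfp157. For Tmem255a they were WT replicate 2 and KO replicates 2 and 3, and for Lrrn3 WT replicate 4 and KO replicate 2. KO replicate 3 did so for Iigp1, WT replicate 2 for AU020206, all other libraries but WT replicate 2 for Dbp and all but KO replicate 4 for Fmo5. The call of Cxcr4 was lost only when WT replicate 3 and KO replicate 1 were both left out (adjusted p = 0.073, in a range from 4.73e-07).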

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

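Among 364 groups of 4 libraries 17 held a library far from the other 3, judged by its gap to the nearest one as a share of the group's range, where chance alone gives about 1 in 20, or 18.2. WT replicate 3 had 6407924 counts (other WT libraries 11610000 to 11950000, gap 0.938 of the range) and 11813 genes with counts (13300 to 13480, gap 0.891). KO replicate 1 stood apart with 70.4 CPM of Srm (46.8 to 49.4, gap 0.889), 10.96 CPM of the amino acid transporter gene Slc43a2 (23.6 to 24.9, gap 0.905), 1500 CPM of Cd36 (886 to 979, gap 0.849) and 1078 CPM of Rps3 (986 to 1000, gap 0.843). It also had 143.7 CPM of the TCA cycle gene Idh3b (86.2 to 90.3, gap 0.928), and KO replicate 4 had 195.9 CPM of Mdh2, of the same list (218 to 219, gap 0.948). KO replicate 2 had 295 CPM of Efnb2 (407 to 419, gap 0.903). KO replicate 3 had 372 CPM of Gapdh (342 to 343, gap 0.957), 19.3 CPM of Sesn1 (30.9 to 32.1, gap 0.907), 96.0 CPM of the aerocyte marker Fibin (25.2 to 30.0, gap 0.932) and 341 CPM of Lyz1 (105 to 117, gap 0.952). KO replicate 4 had 201 CPM of Mcm6 (128 to 135, gap 0.908) and 200.7 CPM of the ribonucleotide reductase gene Rrm1 (142 to 152, gap 0.8294). WT replicate 4 had 4988 CPM of Col4a1 (5515 to 5601, gap 0.859) and 1.98 CPM of Gdf15, which was at 0 in the other 3 WT libraries (gap 1).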

How the results depend on the processing

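The alveolar covariate, the fit without WT replicate 3 and KO replicate 1, the thinning, the length and GC correction and the newer edgeR dispersion option were chosen after the data were seen. Against 461 changed genes (285 higher, 176 lower), DESeq2, which also applied its own low-count filter, called 863 (460 higher, 403 lower), 861 of them among the 12689 genes tested by edgeR, and edgeR with the newer dispersion option 747 (450 higher, 297 lower), holding 458 and all 461 of the genes in the same direction. A 2-fold minimum left 190 (114 higher, 76 lower) and a threshold of 0.01 left 206 (130 higher, 76 lower), by their construction. Removing the length and GC trend left 285 genes (129 higher, 156 lower), 258 of them shared, and the cause of the loss was not tested. Leaving out 1 library gave 270 to 446 changed genes, 173 to 259 higher and 97 to 187 lower, with the lowest values all without KO replicate 3. All 8 such totals were below 461, as fewer samples tend to give, though lower genes numbered 187 without KO replicate 1. Lower genes were also few without KO replicate 2 (105) and WT replicate 2 (111). The other alternatives stayed within 1.5 times of each count. The labels do not state whether replicate numbers pair the samples. Same-numbered libraries correlated at -0.0871, -0.132, 0.0155 and -0.0131 over 10692 genes, and not every library correlated best with its own number. Correlations between all WT and KO libraries were weak (-0.165 to 0.124), so pairing did not show but cannot be excluded. With the replicate number as a block 338 genes changed (215 higher, 123 lower), 323 of them shared.

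Of the 27 lists past camera 1, the tRNA synthetases, passed with an estimated correlation, and did so in 9 of 23 alternatives. Of these 9, the newer dispersion option repeats the main camera result by construction. By fry, which tests whether a list's genes move one way and not against other genes, 13 passed. The calls of 14 lists ended by fry (adjusted p from 0.0595 to 0.452). They were complex I, IV and V, mitochondrial DNA genes, mitochondrial ribosomal proteins, both cell cycle lists, angiogenic sprouting and endothelial activation. The immediate early, pan-endothelial, arterial, venous and fibroblast lists were the others. With the alveolar covariate and an estimated correlation glycolysis and general capillary passed instead (both 0.0253). Leaving out 1 library gave 22 to 27 lists, and the length and GC correction 20. Uqcrq stayed lower and short of the transcriptome-wide threshold throughout. Its log2 fold change was -1.69 to -1.06 without single libraries and its adjusted p 0.0522 to 0.333 over 24 alternatives. Of 87 genes past the threshold that the naming rule covers, 50 passed under every alternative, 37 lost the call under at least 1 and 0 changed direction. Thinned to the total of the shallowest library, the counts gave 468 changed genes (278 higher, 190 lower), 442 of them shared, and of these 87 calls that of Hif1a was lost (adjusted p = 0.0528). Apart from single libraries, most of these losses came with WT replicate 3 and KO replicate 1 both left out (21 genes, adjusted p up to 0.187), the replicate block (17 genes, up to 0.261), the length and GC correction (15 genes, up to 0.622) and limma voom (12 genes, up to 0.205). With the block they were Gdf15, Srm, Tmem255a, Chac1, Zfp157, Fmo5, Dbp, Ndufa11, mt-Nd2, Cs, Uhrf1, Epas1, Hif1a, Sesn1, Btg2, Jun and Erg. With the length and GC correction they were Gdf15, Tmem255a, Chac1, Ndufa11, mt-Co1, mt-Nd1, mt-Nd2, Cs, Plk1, Ckap2l, Uhrf1, Hif1a, Mcam, Col4a1 and Gata2.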

Other observations

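Apart from the count of splits, the tests in this part were chosen after the pattern they bear on was seen, though member values of the 3 further gene lists had not been looked at. The first further list, 39 tested genes of actin, tubulin and focal adhesions, was written because several actin-binding and lamin genes stood among the top genes. It had 13 members higher and 0 lower by edgeR with Benjamini-Hochberg adjustment (21 when adjusted over the list alone), 35 of 39 with a positive change and a median log2 fold change of 0.45. Vim, which encodes the intermediate filament vimentin, rose from 2252 to 3707 CPM and Myh9, a nonmuscle myosin gene, from 911 to 1690 CPM (means of 4 libraries). Camera, adjusted over the 3 further lists, gave an adjusted p of 2.18e-10, and adjusted p = 0.000897 with an estimated correlation (0.0159 when adjusted over all 53 lists tested). Over all lists it passed in 18 of 23 alternatives, and not without WT replicate 4 (0.0592) or KO replicate 1 (0.0603), nor with the replicate block (0.212), among others. With the length and GC trend removed 4 members were called, the median was 0.32 and the list did not pass with an estimated correlation (adjusted p = 0.0771, in a range from 0.000587), though it did with the preset one (5.91e-07). Genes named here were chosen after their values were seen.

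The other lists asked whether the rise of ribosomal protein and tRNA synthetase genes extends to other genes of the protein synthesis machinery. All 40 tested ribosome biogenesis genes had a positive change, with a median log2 fold change of 0.70. By edgeR 2 of them passed singly (6 when adjusted over the list alone): Fbl, the fibrillarin gene, from 19.4 to 51.1 CPM, and Mybbp1a from 74.1 to 135 CPM. The list passed with adjusted p = 0.00339 with an estimated correlation and in each of 23 alternatives (up to 0.0283 with the replicate block). Adjusted over all 53 lists it had 0.0399 and passed in 14 of the 23. It then failed with the replicate block (0.212), with the Y-linked level as a covariate (0.0609) and without WT replicate 2 (0.0703) or 4 (0.0946) or any 1 KO library (0.0603 to 0.0825), among others. Of the single calls 1 was left without WT replicate 1, 2 or 3 or KO replicate 4 and 0 without WT replicate 4 or KO replicate 2 or 3. Of 26 translation factor genes 8 rose (16 when adjusted over the list alone), 25 had a positive change and the median was 0.43, with adjusted p = 0.00493 with an estimated correlation (0.0538 over all 53 lists, with 3 of 23 alternatives past the threshold). Eif2s2 rose from 103 to 194 CPM and Eef1b2 from 269 to 447 CPM. Without WT replicate 2, 3 or 4 or KO replicate 3 or 4, 4 of these genes were called. With the length and GC trend removed 1 translation factor gene was called, the median was 0.32 and that list did not pass with an estimated correlation (adjusted p = 0.0771, in a range from 0.00361). The ribosome biogenesis list then had a median of 0.61 and passed (0.00117, or 0.0207 over all 53 lists), which argues against that trend as the whole cause of its rise. Whether these lists pass otherwise depended on the setting and on the lists adjusted over.

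Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many as the 461 changed genes, the real one. The highest other split gave 5. A rank of 1 in 35 is the most that 8 libraries can give, so chance is made unlikely but not excluded. The other splits mix WT and KO libraries, and any difference between the groups then adds to the spread and lowers their counts. The count of splits does not tell genotype from another difference between the groups. Y-linked genes were at 152 to 220 CPM in WT replicates 1 and 4 and KO replicates 2 and 4 and at 0.345 to 3.59 CPM in the other libraries. WT replicate 4 held 107 counts of Xist along with 1821 of Y-linked genes, where WT replicate 1 and KO replicates 2 and 4 held 0 of Xist. Whether WT replicate 4 mixes animals of both sexes was not tested, and without it 331 genes changed (199 higher, 132 lower). Sftpc, the surfactant protein C gene of alveolar type 2 cells, ranged from 2245 CPM in KO replicate 1 to 15370 CPM in WT replicate 1, although cells were sorted for CD31.

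The first pattern weighed is the rise of ribosomal protein genes in KO. Total counts averaged 10472000 ± 2713500 in WT and 12707000 ± 1142600 in KO (SD, n = 4 each, exact permutation p = 0.114, adjusted p = 0.229). KO replicate 1, at 11209714, was not deeper than most WT libraries. Thinning all libraries to one depth kept 57 of the 61 called members. With the alveolar type 2 marker level as a covariate the list's median log2 fold change was 0.69 against 0.65. The totals and the thinning argue against differences in depth as the cause. The alveolar share hardly differed between the groups (exact permutation p = 0.429), so the covariate could hardly move the genotype effect and adds little. Alveolar shares overlapped (0.423% to 2.41% in WT, 0.384% to 1.72% in KO). Ribosomal protein shares did not (2.30% to 2.91% in WT, 3.97% to 4.18% in KO), which argues against alveolar RNA as the whole cause. A trend of the libraries with transcript length and GC content stays open: after its removal 20 of the 61 members were called, their median falling from 0.70 (0.47 to 1.36) to 0.50 (0.18 to 1.10) while the median SE went from 0.135 to 0.155, so that calls ended through smaller changes and larger errors. The list still passed camera with the preset correlation (adjusted p = 1.35e-28), but with an estimated correlation it passed neither before (adjusted p = 0.121) nor after (0.243), and the correction can also remove a true change of short genes, so the share of the rise that is technical cannot be told apart from an effect of genotype. Reads shared with processed pseudogenes were not tested.

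The second pattern is the fall of general capillary markers. Alveolar type 2 markers took 1.43 ± 0.872% of counts in WT and 0.999 ± 0.578% in KO (SD, n = 4 each). Dilution by alveolar RNA would then lower capillary markers in WT rather than in KO, which argues against it as the cause. With the alveolar type 2 level as a covariate the capillary list's median was -0.79 against -0.75. As KO held less alveolar RNA on average, that fit could hardly show dilution and adds little. Dilution by RNA of other cells was not tested. A smaller share of general capillary cells would lower the markers together, yet their changes differed by more than their errors (chi-square test of heterogeneity, p = 2.446e-15 over 12 genes), from -1.51 for Cadm1 to 0.51 for Cd93. As markers differ in how far other endothelial cells express them, and the rise of Cd93 did not pass the threshold over all genes, this leaves open both a smaller share of these cells and a change of expression within them. In counts of a whole sorted population these cannot be told apart.

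The third pattern is the Uqcrq signal left in the KO libraries, at 1.59 to 15.6 CPM. If it came from alveolar type 2 cells, in which the gene was not deleted, Uqcrq per alveolar marker count should be alike, but the highest KO library had 4.84 times the ratio of the lowest. Counting error alone left at least 2.61 times between them, whereas with the gene's fitted dispersion the lower limit was 1.01. That dispersion was fitted to the same libraries and grows with their spread, so this limit could hardly exclude alveolar cells as a source. They may still account for part of the signal. Incomplete deletion in endothelial cells and reads from an undeleted part of the gene were not tested, as the sources used here do not give the deleted part.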
